A study of Homo sapiens with 4 samples.

How the data were processed

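CUT&Tag libraries were made from HCT116 cells, a human colon cancer line, with antibodies against H3K27ac in PKM2 wild-type and PKM2 K206R cells and against FOSL1 and PKM2 in PKM2 wild-type cells, with 1 library in each of the 4 groups. Per the labels' protocols, bead-bound cells were incubated with the primary antibody, a secondary antibody and a protein A-Tn5 adapter complex, and the tagged DNA was purified, amplified and sequenced. An IgG library was not analysed here. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and the hg38 build were used. The peak caller, its settings, its control and the annotation tool are not given in the sources used here.

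The deposited files are annotated peak lists, 1 per library, with no pooling of libraries recorded. Per the file headers, each peak has a start, end, length, summit, pileup, p-value, fold enrichment, q-value, annotation class, assigned gene and distance to its TSS. The pileup is a signal, the height of piled-up fragments at the summit, deposited without a recorded scaling to library size. The p-values and q-values are deposited as −log10 values for each peak. The fold enrichment is a ratio of pileup to background, deposited per peak with a pseudocount of 1 in each. The background behind each peak was recovered as (pileup + 1) / fold − 1. A Poisson tail of the pileup over that background gave the deposited −log10 p-values to within 0.0001, and the smallest −log10 p-value in each list was just above 3. The lowest background in a list is the library-wide level. It moves with the number of fragments and with the length to which they were extended, and stood in for depth since read totals are not in the lists. Folds and ranks were used only within their own list. So were scores, apart from fixed cuts on q, which were not adjusted for depth.

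Overlaps were counted from the deposited coordinates with a minimum of 1 bp. Shares have Wilson 95% intervals. Each was set beside 200 random placements of the second list's peaks on their own chromosomes. A promoter gene has a peak that the deposited annotation assigns to it at most 2 kb from its TSS. Shares of promoter peaks use the deposited promoter class, which reaches 3 kb. TSS positions came from the gene coordinates and strands in the 4 files, so genes assigned to no peak in any library have none, and are left out of the lists' counts. Of 21626 gene symbols, 21360 matched the RefSeq gene table, which gave gene types and the spans of FOSL1 and PKM. Covered length per gene was summed within 5 kb of its TSSs (and within 2 kb and 50 kb). The 17 gene lists were fixed before the data were examined. For each, the median difference between libraries was set among 10000 random lists of protein-coding genes of the same size matched on covered length, as a description of these libraries. Super-enhancer-like domains were built from peaks more than 2.5 kb from a TSS, stitched within 12.5 kb, ranked by the sum of pileup times length, and called above the point where the scaled rank curve has a slope of 1. They rest on peak lists and not on reads. Retention compares the share of wild-type H3K27ac peaks found in K206R with and without a binding peak, within deciles of the wild-type −log10 q. Odds ratios were pooled over the same deciles by the Mantel-Haenszel method.

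Genes named in the text follow rules set before the data were examined, with exceptions stated where they occur. The rules took FOSL1 and PKM in every library, the 12 promoter genes of highest fold in each H3K27ac list with no peak of the other list within 2 kb of the TSS, the assigned genes of the 10 top wild-type domains and of the 6 top domains of each genotype without a counterpart, the genes of the 10 highest FOSL1 peaks, the 10 highest PKM2 peaks and the 10 highest FOSL1 peaks inside both other lists, and up to 4 members per gene list, first those listed in 1 genotype alone and then by difference in covered length. Members of a list named beyond these 4 complete a count or were chosen after their values were seen.

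The scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data built on the 34503 wild-type H3K27ac peaks. A planted overlap of 59.4% was recovered as 59.6%, a planted retention difference of 10 points as 9.04 points and a planted odds ratio of 3 as 3.07. The alternatives were a −log10 q of at least 10, equal numbers of peaks, at least 50% overlap, a distance of 1 kb, the main chromosomes only, other promoter windows, other stitching and ranking for domains, and other strata for retention. Chosen after seeing the data were the removal of peaks called in all 4 libraries, the removal of H3K27ac peaks with both FOSL1 and PKM2 from retention, a q under 0.05, a promoter rule by coordinates and K206R peaks thinned to 78.7% of their height, the ratio of the library-wide backgrounds. No genome sequence was used here, so the search for AP-1 motifs under FOSL1 peaks was not run.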

Results

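Histone H3 lysine 27 acetylation (H3K27ac), a mark of active promoters and enhancers, was profiled by CUT&Tag in HCT116 human colon cancer cells carrying either wild-type PKM2 or the PKM2 K206R mutant. In CUT&Tag, an antibody directs a transposase to its target, which cuts and tags the DNA around it for sequencing. FOSL1, an AP-1 transcription factor, and PKM2, the pyruvate kinase isoform typical of tumour cells, were profiled in the PKM2 wild-type cells. Each of the 4 groups held 1 library, so no difference between groups has a replicate check and no p-values are given. Intervals on shares are 95% Wilson intervals and cover counting error only. The peak lists gave no read totals. The lowest background level behind any peak, in piled-up fragments, was 1.89 in the wild-type H3K27ac library, 2.40 in the K206R H3K27ac library, 1.34 in the FOSL1 library and 1.48 in the PKM2 library. All 4 lists held peaks down to a −log10 p of 3. Of the H3K27ac peaks, 95.7% in wild-type and 97.9% in K206R cells had a q-value under 0.05, against 1581 of 6755 FOSL1 peaks (23.4%) and 1984 of 7949 PKM2 peaks.

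The first comparison addressed how the PKM2 K206R mutant affects the H3K27ac landscape. Nearly all strong H3K27ac peaks of either genotype overlapped a listed peak of the other, and most peaks without a counterpart were weaker. With no replicate, how many such peaks would differ between libraries of the same genotype is not known. Of the 3150 wild-type peaks with a −log10 q of at least 10, 3145 overlapped a K206R peak (99.8%, 99.6 to 99.9). The strong K206R peaks were found in wild-type cells in 7088 of 7303 cases (97.1%, 96.6 to 97.4). The K206R list was the longer of the pair, with 45036 peaks covering 31.8 Mb against 34503 peaks covering 23.6 Mb. Mean peak length was 707 bp in K206R and 684 bp in wild type. The covered length was 1.35 times that of wild type, and the background level was 1.27 times that of wild type.

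Over all peaks, 60.4% of the wild-type peaks overlapped a K206R peak by at least 1 bp (59.8 to 60.9, n = 34503), against 2.24% when the K206R peaks were placed at random. In the reverse direction, 46.0% of the K206R peaks overlapped a wild-type peak (45.6 to 46.5, n = 45036), against 1.72% at random. Sharing followed peak strength within each list. It went from 23.2% in the weakest decile of wild-type peaks to 99.8% in the strongest, and from 12.9% to 98.9% among the K206R peaks. Wild-type peaks found in K206R cells lay at annotated promoters in 55.0% of cases and had a median length of 718 bp. The 13677 wild-type peaks without a K206R counterpart lay at promoters in 23.5% of cases, with a median length of 445 bp. The 24298 peaks listed in K206R cells alone were similar to these, with 27.1% at promoters and a median length of 462 bp. With only peaks of −log10 q of at least 10 in both lists, the covered-length ratio was 2.41. Then 93.9% of the wild-type peaks were found among the K206R peaks and 40.5% of the K206R peaks among the wild-type peaks. The same cut was applied to both lists, with no adjustment for the K206R background level of 1.27 times that of wild type.

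**Figure D1:**
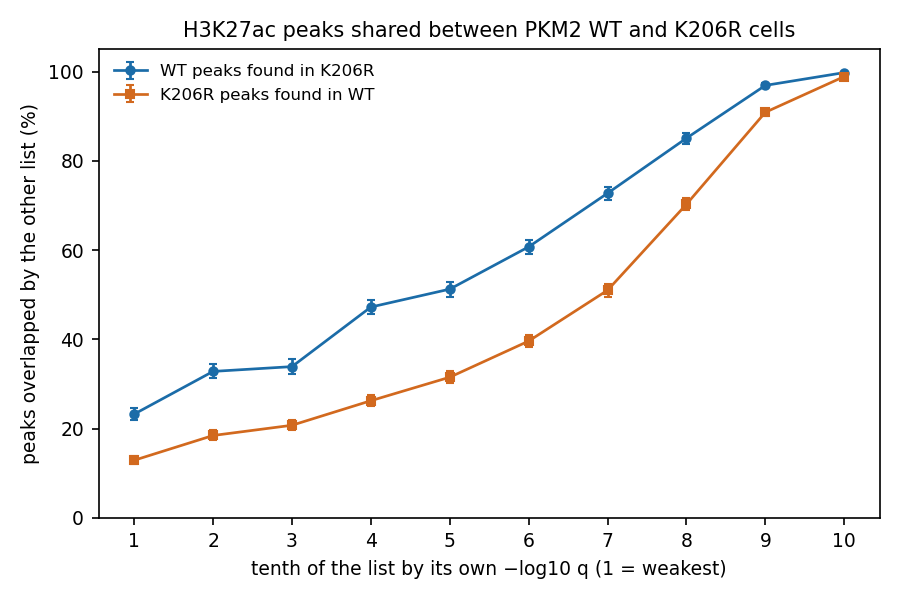
Percentage of H3K27ac peaks in each decile of a list (x axis, by the list's own −log10 q, 1 = weakest) that overlapped a peak of the other genotype (y axis). Points are shares, bars are 95% Wilson intervals, and the lines run from 23.2% to 99.8% for wild-type peaks and from 12.9% to 98.9% for K206R peaks.

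The 5 strong wild-type peaks without a K206R counterpart were examined by position, a choice made after their values were seen. They lay in an intron of COL23A1 (chromosome 5, 178585481 to 178585849), in introns assigned to PPP3CA (chromosome 4, 101217244 to 101217931) and OTOS (chromosome 2, 240232867 to 240233488), in the promoter region of LERFS (chromosome 9, 62882951 to 62883455) and in an intergenic stretch of chromosome 1 (125179656 to 125180350). The chromosome 1 site, assigned to EMBP1, also held FOSL1 and PKM2 peaks that were among the highest of their lists. Of the 215 strong peaks listed in K206R cells alone, 122 were promoter peaks (56.7%, 50.1 to 63.2). Those with the highest −log10 q at a gene promoter were at SNORD3D, a small nucleolar RNA gene (34.3), THAP11, a zinc-finger transcription factor gene (24.3), and PSTK, which encodes a kinase of selenocysteine synthesis (21.8). Away from promoters, the highest were assigned to NID1 (−log10 q 51.5), SSTR5-AS1 (28.6) and IQGAP1 (23.1). MET, the hepatocyte growth factor receptor gene, held a lower one (chromosome 7, 116776272 to 116777502, annotated as 3′ UTR, −log10 q 21.2). It was named after the values were seen. The MET promoter itself carried H3K27ac in both genotypes.

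At promoters, most genes with H3K27ac had it in both genotypes. A promoter peak, assigned by the authors to the gene and within 2 kb of its transcription start site (TSS), was listed in both libraries for 9679 of 13852 genes (69.9%). It was listed in the K206R library alone for 2833 genes (20.5%, 19.8 to 21.1) and in the wild-type library alone for 1340 genes (9.67%, 9.19 to 10.2). Among the 12 wild-type-only genes of highest deposited fold enrichment were LACC1, an immunometabolic enzyme gene (6.35), HMGCLL1, a ketone body enzyme gene (6.24), SLCO4C1, an organic anion transporter gene (5.44), FLVCR2, a choline and putative heme transporter gene (5.34), and CCDC92B (5.21). The others were GTF2IP12, MIR3920, SNX29P2, LOC107985561, SLC28A2-AS1, CD200R1L and MOV10L1, with folds from 5.31 to 6.24. Among the 12 K206R-only genes were SNORD3D (13.0), NXT2, an RNA export factor gene (7.95), IFT70B, an intraflagellar transport gene (7.49), ZNF264 (6.84), N6AMT1, a methyltransferase gene (6.53), PTPRK, a receptor tyrosine phosphatase gene (6.48), and VBP1, a prefoldin subunit gene (6.39). The others were the pseudogenes SDHAP3, STAG3L5P and ZNRF2P1 and the noncoding RNA genes LINC01098 and LINC02613, with folds from 6.36 to 8.24. The folds are the authors' values for single peaks and were not set against each other across libraries. With K206R peaks thinned to the wild-type background level, a setting chosen after seeing the data, the counts were 1464 wild-type-only and 2571 K206R-only genes. With the same number of peaks from each list they were 1619 and 2164, and with a −log10 q of at least 10 in both lists 156 and 3002. The q cut was not adjusted for the higher K206R background level.

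Gene lists fixed beforehand were then described by the promoter peaks of their members. Over all protein-coding genes with H3K27ac within 5 kb of a TSS, the median covered length was 858 bp in wild type and 1096 bp in K206R, and 70.9% had more in K206R. The lists are therefore set against random lists of genes matched on covered length. Each of the 17 lists had its own random range, and neither ranges nor percentiles were adjusted for the number of lists. Some lists can therefore fall outside by chance, and a place outside does not by itself set a list apart. By percentile, the glycolysis and lactate list stood highest above its matched lists. Of its 21 genes with a listed TSS, 13 had a promoter peak in both genotypes, 4 in K206R alone, none in wild type alone and 4 in neither. Its median difference in covered length, K206R minus wild type, was 708 bp, against 0 to 545 bp in the central 95% of matched lists (percentile 99.8). Covered length was 732 bp in wild type and 1976 bp in K206R at TPI1, 1304 and 2149 bp at ENO1, 0 and 773 bp at PFKM, and 486 and 1072 bp at ALDOC, all genes of glycolytic enzymes. With the same number of peaks from each list the median was 385 bp and inside its random range of 0 to 406 bp. At 50 kb around the TSS it was 1239 bp and also inside.

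The list of acyltransferases and deacylases lay below its matched lists, with a median difference of -35 bp against -17.5 to 416 bp (percentile 1.65). This percentile too was not adjusted for the number of lists. It held 9 genes with a promoter peak in both genotypes, 2 in wild type alone, 3 in K206R alone and 4 in neither. EP300, which encodes the p300 acetyltransferase, had 1735 bp in wild type and 0 bp in K206R, and HDAC3 had 356 and 0 bp. SIRT6, a deacylase gene, had 0 bp in wild type and 1338 bp in K206R, KAT2A had 0 and 404 bp, and NAA10 had 893 and 364 bp. The list was inside the random range with the same number of peaks from each list (-35 bp, range -72.0 to 382 bp) and within 2 kb and 50 kb.

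The other 15 lists lay inside the random range in the 5 kb window. Among the AP-1 genes, 9 of 15 had a promoter peak in both genotypes, including FOSL1, FOS, FOSB, FOSL2 and ATF3. JUNB (416 bp in wild type, 1662 bp in K206R), MAFG (0 and 961 bp) and BATF3 (404 and 965 bp) were listed for K206R alone, and JUN (1358 and 1710 bp) for wild type alone. Peaks within 2 kb of the JUN and JUNB start sites, whatever gene they were assigned to, were listed in both genotypes. This was also so for ENO1, NAA10, FN1, GATA6, KRT18, DKK1, RPL8 and RPS3. Of 36 genes of angiogenesis and of vasculogenic mimicry, the lining of vessel-like channels by tumour cells, 19 had promoter H3K27ac in both genotypes, 8 in K206R alone and none in wild type alone. The 8 included DLL4, a Notch ligand gene (0 and 729 bp), NRP2, a VEGF co-receptor gene (834 and 1526 bp), FGF2 (0 and 589 bp) and PROM1 (0 and 571 bp). VEGFA had promoter peaks in both, with 717 bp in wild type and 2438 bp in K206R. Of the 36 genes, 21 had more covered length in K206R and 9 had less, among them PLAUR (3298 and 2325 bp) and NRP1 (1116 and 661 bp). The list's median difference was 341 bp against 0 to 412 bp at random (percentile 89.2).

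The epithelial-mesenchymal transition list had 8 of 20 genes in both, 7 in K206R alone and 2 in wild type alone. TGFBI (0 and 1705 bp), TGFBR1 (0 and 888 bp) and TGFB2 (0 and 527 bp) were listed for K206R alone, and FN1 (351 and 886 bp) for wild type alone. Colonic epithelial genes were listed in both genotypes for 16 of 26 genes and in K206R alone for 5. These included GATA6 (450 and 1372 bp), CDH17 (0 and 358 bp), TFF3 (478 and 710 bp) and KRT18 (1835 and 1666 bp). WNT pathway targets were listed in both for 12 of 19 genes, in K206R alone for 3, among them ZNRF3 (0 and 2386 bp), DKK1 (1719 and 2246 bp) and NOTUM (870 and 611 bp), and in wild type alone for APCDD1 (447 and 0 bp). YAP-TEAD targets were listed in both for 18 of 23 genes, in K206R alone for NUAK2 (0 and 1093 bp) and TGFB2, and in wild type alone for CRIM1 (545 and 0 bp). AJUBA, listed in both, had 399 and 2999 bp.

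Hypoxia targets were listed in both genotypes for 13 of 22 genes and in K206R alone for 5, among them PFKFB4 (0 and 1483 bp), P4HA2 (0 and 1056 bp), BNIP3 (0 and 848 bp) and LOX (0 and 706 bp). Genes of the enhancer and Mediator machinery were listed in both for 11 of 17 genes and in K206R alone for MED12 (0 and 1262 bp), BRD3 (0 and 1017 bp), MED1 (0 and 468 bp) and KMT2C (439 and 715 bp). The immediate early and p53 target lists had more wild-type-only than K206R-only members, 4 against 2 and 3 against 1. Among the immediate early genes these were DUSP6 (1440 and 2449 bp), IER2 (1330 and 585 bp), SPRY2 (731 and 0 bp) and DUSP1 on the wild-type side and ETV5 (412 and 1880 bp) and ZFP36 on the K206R side. Among the p53 targets they were BTG2 (1180 and 1969 bp), POLH (931 and 552 bp) and BBC3 (1319 and 1186 bp) against RRM2B (0 and 522 bp). By position alone, DUSP6, DUSP1, IER2, BTG2 and POLH had peaks within 2 kb in both genotypes, and the counts were 1 against 2 and 1 against 1. Ribosomal protein genes were listed in both for 19 of 23 genes, in K206R alone for RPL8 and RPS3 and in wild type alone for RPL14 (1062 and 750 bp). Their median difference was 22 bp against 13 to 465 bp at random (percentile 3.09). Within 2 kb it was 0 bp and below its random range of 2.98 to 379 bp (percentile 2.28).

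Markers of other cell types served as background. K206R-only members were also found among endothelial markers, at 4 of 13 genes (KDR, TIE1, EMCN and CLDN5), and among blood cell markers, at 3 of 9 genes, including ITGAM (0 and 968 bp) and HBB (0 and 362 bp). KDR and TIE1 are also in the vasculogenic mimicry and angiogenesis list, so the endothelial count is not independent of that list. Fibroblast and muscle markers had COL1A2 (0 and 818 bp) in K206R alone and MYH7 (561 and 0 bp) in wild type alone among 8 genes. Neural and liver markers had 4 of 10 genes in both and none in 1 genotype alone. MBP, a myelin gene listed in both, had 4535 and 7280 bp.

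**Figure D2:**
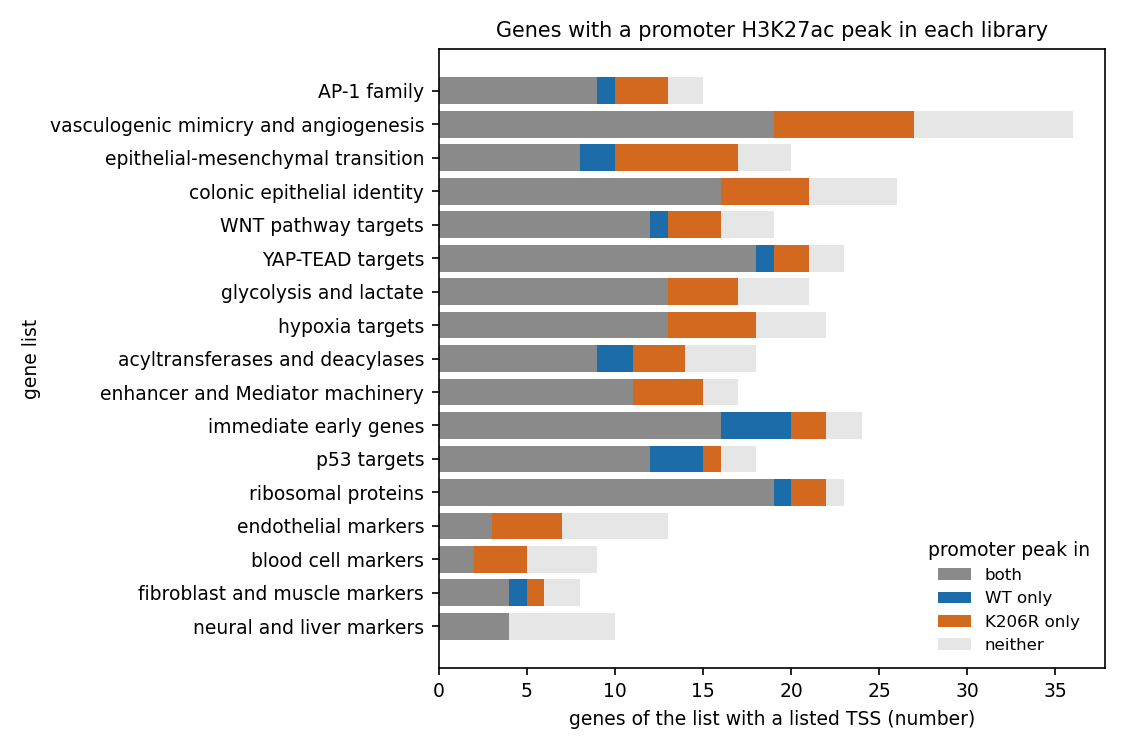
Number of genes with a listed TSS (x axis) in each gene list (y axis), divided by the library in which a promoter H3K27ac peak was listed. K206R-only genes outnumbered wild-type-only genes in 13 of the 16 lists with either, and wild-type-only genes outnumbered them in 2.

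The next comparison concerned super-enhancers, long clusters of strong enhancer peaks, which the study's title links to FOSL1. H3K27ac peaks more than 2.5 kb from a TSS were stitched into domains and ranked within each library by pileup times length. This gave 606 super-enhancer-like domains among 16648 in wild type and 481 among 20978 in K206R. Many were short: the median was 2 peaks over a span of 10.2 kb in wild type and 3 peaks over 16.7 kb in K206R. Some were single peaks. Of the wild-type domains, 68.6% overlapped a K206R super-enhancer-like domain (64.8 to 72.2, n = 606) and 99.3% overlapped any K206R domain. Of the K206R domains, 82.1% overlapped a wild-type one (78.4 to 85.3, n = 481). FOSL1 peaks lay in 26.9% of the wild-type super-enhancer-like domains and in 5.57% of the other domains. PKM2 peaks lay in 20.8% and 6.33%. Super-enhancer-like domains are longer by how they were chosen, and these shares were not adjusted for length.

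All 10 top-ranked wild-type domains were overlapped by a K206R super-enhancer-like domain. They were assigned to MIR3918, ZDHHC6, PCDH7 (a protocadherin gene), PLEKHG4B, MYOF (a membrane repair gene), MIR31HG (the host gene of miR-31), NSMCE2, LOC107986229, LOC107986198 and LINC02458. The PCDH7 domain (chromosome 4, 30802385 to 30914272) held 18 peaks over 13703 bp in wild type and 26 peaks over 19822 bp in K206R. The PLEKHG4B entry was a single peak at the end of chromosome 5 (10052 to 11741), called in all 4 libraries. The 6 top-ranked wild-type domains without a K206R super-enhancer-like domain were assigned to KRT78 (a keratin gene), LRP5 (a WNT co-receptor gene), TOB1, CASC19, KCNK3 and MIR5702. Each still held K206R peaks. The LRP5 domain (chromosome 11, 68342210 to 68355120) had 3223 bp covered in wild type and 1584 bp in K206R, and the TOB1 domain 4364 and 2467 bp. The MIR5702 domain had 2173 and 1929 bp, and the CASC19 domain 1517 bp in both, so a missing call did not always go with less coverage. The 6 of the reverse were assigned to MIR222HG, the host gene of miR-221 and miR-222, and to MIR4296, MIR100HG, LINC02003, CMTM7 and SSH1. The MIR222HG domain (chromosome X, 45734921 to 45825219) had 16 peaks over 10572 bp in K206R and 3 peaks over 2138 bp in wild type. The LINC02003 domain on chromosome 17 had 6616 bp in K206R and 2176 bp in wild type. With stitching within 5 kb, the numbers were 666 and 1062, so the order of the genotypes turned. With ranking by covered length, the overlapped share of wild-type domains was 41.3%.

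FOSL1 itself (chromosome 11, 65892049 to 65900545, hg38) carried H3K27ac in both genotypes. The promoter peak spanned 945 bp in wild type (65899438 to 65900382) and 1262 bp in K206R (65899297 to 65900558). A super-enhancer-like domain lay beyond the TSS end of the gene in both, and the authors' annotation assigned both of its peaks to C11orf68, not to FOSL1. Its larger peak had the promoter class in both. This peak lay 2871 bp from the C11orf68 TSS in wild type and 2712 bp in K206R, just beyond the 2.5 kb exclusion. The domain began 11.2 kb from FOSL1 in wild type (65911729 to 65916191, 2 peaks over 1668 bp, rank 309 of 16648 domains). In K206R it began 10.9 kb from the gene (65911469 to 65916350, 2 peaks over 2064 bp, rank 345 of 20978 domains). The ranking used pileup without taking off the background. By fold enrichment its peaks were weak, at 2.28 and 2.30 in wild type against a list median of 3.44. In K206R they were 1.95 and 2.74, against a list median of 3.28. The only FOSL1 peak within 50 kb of the gene fell in this domain (65915264 to 65915697, fold enrichment 3.06, −log10 q 0.978). No PKM2 peak was listed within 50 kb. Over the gene and 50 kb on either side, 8 wild-type peaks covered 5433 bp and 13 K206R peaks covered 9120 bp. The domain was called in wild type under all 5 alternative settings for domains and in K206R under 4 of 5. For wild type, taking the same number of peaks from each list changed nothing, since its list is the shorter. The exception was ranking by covered length, where the K206R domain ranked 886 with 441 domains called. The wild-type domain then ranked 787 with 787 called, the last to pass.

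**Figure D3:**
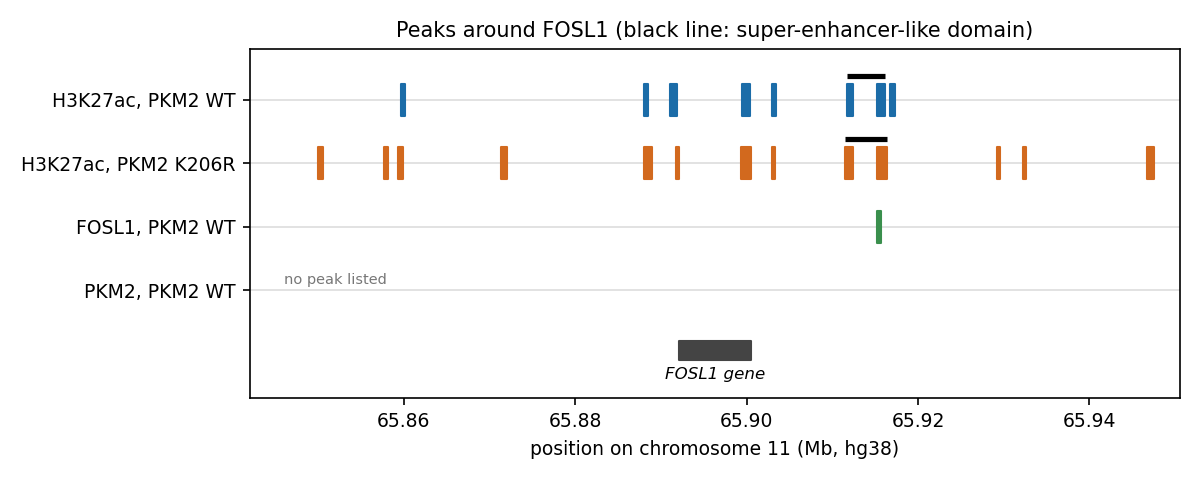
Peaks of the 4 libraries (rows) along chromosome 11 (x axis, Mb, hg38) over FOSL1 and 50 kb on either side; coloured blocks are listed peaks and black lines are super-enhancer-like domains. Both H3K27ac libraries show the promoter peak and the domain, 1 FOSL1 peak falls in the domain, and no PKM2 peak is listed.

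PKM, the gene that encodes PKM2 (chromosome 15, 72199029 to 72231591), had 3 promoter peaks in wild type over 2175 bp and 2 in K206R over 2284 bp. An H3K27ac peak 5.24 kb beyond the gene (72236826 to 72238066, 1241 bp) ranked 474 among the wild-type domains and was called super-enhancer-like. The corresponding K206R peak (72236768 to 72238066, 1299 bp) ranked 551, with 481 domains called. The calls rest on each library's own ranking and cut. No PKM2 peak was listed within 50 kb of PKM. A FOSL1 peak lay at PARP6 in that window (72267510 to 72268032, −log10 q 0.407).

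The remaining comparisons asked where FOSL1 and PKM2 were called relative to active chromatin and to each other. Both proteins were listed mainly away from promoters. Of the 6755 FOSL1 peaks, 39.2% were in introns, 31.5% intergenic and 23.2% at promoters. The 7949 PKM2 peaks were divided likewise, with 39.7%, 34.2% and 20.2%. FOSL1 peaks lay in wild-type H3K27ac peaks in 26.5% of cases (25.4 to 27.5, n = 6755), against 1.44% at random, and PKM2 peaks in 23.5% (22.6 to 24.5, n = 7949), against 1.40%. The share went from 15.4% in the weakest decile of FOSL1 peaks to 54.4% in the strongest, and from 12.7% to 47.2% for PKM2. Among peaks with q under 0.05, a setting chosen after seeing the data, the shares were 43.3% and 36.9%. With as many H3K27ac peaks as binding peaks, the strongest of each list, they were 11.3% and 9.55%. Near genes of the fixed lists, the number of genes with FOSL1 or PKM2 peaks was not outside the range of matched random genes for any list. Within 50 kb of a TSS, FOSL1 peaks were listed for 12 of 36 vasculogenic mimicry and angiogenesis genes (random range 9 to 20) and for 7 of 15 AP-1 genes (3 to 10). PKM2 peaks were listed for 7 of 21 glycolysis and lactate genes (5 to 13) and for 15 of 26 colonic epithelial genes (6 to 16).

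The peaks of highest fold were not at typical genes. The 10 highest FOSL1 peaks had folds from 12.7 to 19.1, and 8 of the 10 were called in all 4 libraries. They included positions at a chromosome end (chromosome 10, 10011 to 10367, assigned to TUBB8 38.9 kb away), near a centromere (chromosome 16, 46389846 to 46391395, assigned to ANKRD26P1, and chromosome 5, 49601484 to 49602676, assigned to EMB 809 kb away) and at ribosomal DNA (chromosome 21, 8219535 to 8220404, assigned to RNA5-8SN2). The others were assigned to DDX11L16, MIR6724-2, EMBP1, LOC124903767 and FRG1CP. The 10 highest PKM2 peaks had folds from 13.7 to 18.0, and 6 of the 10 were called in all 4 libraries. They shared the sites at DDX11L16, ANKRD26P1, TUBB8, MIR6724-2 and EMBP1, and the others were assigned to LOC107985200, FRG2B, ANHX and LOC105375937. The 10 highest FOSL1 peaks inside both PKM2 and wild-type H3K27ac peaks were all assigned to genes named above.

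FOSL1 and PKM2 peaks coincided at 599 of 6755 FOSL1 peaks (8.87%, 8.21 to 9.57), against 0.278% at random. All 51 FOSL1 peaks with a −log10 q of at least 10 were among them (100%, 93.0 to 100), and 52 of 55 such PKM2 peaks overlapped a FOSL1 peak. Of the 599, 356 were called in all 4 libraries. Without these the share was 3.72%, which is lower by construction, since every peak left out overlapped a PKM2 peak. Inside wild-type H3K27ac peaks, 21.9% of those with a FOSL1 peak had a PKM2 peak, against 4.53% of those without. The odds ratio pooled over deciles of H3K27ac score was 4.56 (4.01 to 5.19), not adjusted for the length of the H3K27ac peaks. H3K27ac peaks with a FOSL1 peak were promoters in 42.2% of cases and those with a PKM2 peak in 40.6%, against 42.5% of all wild-type H3K27ac peaks.

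**Figure D4:**
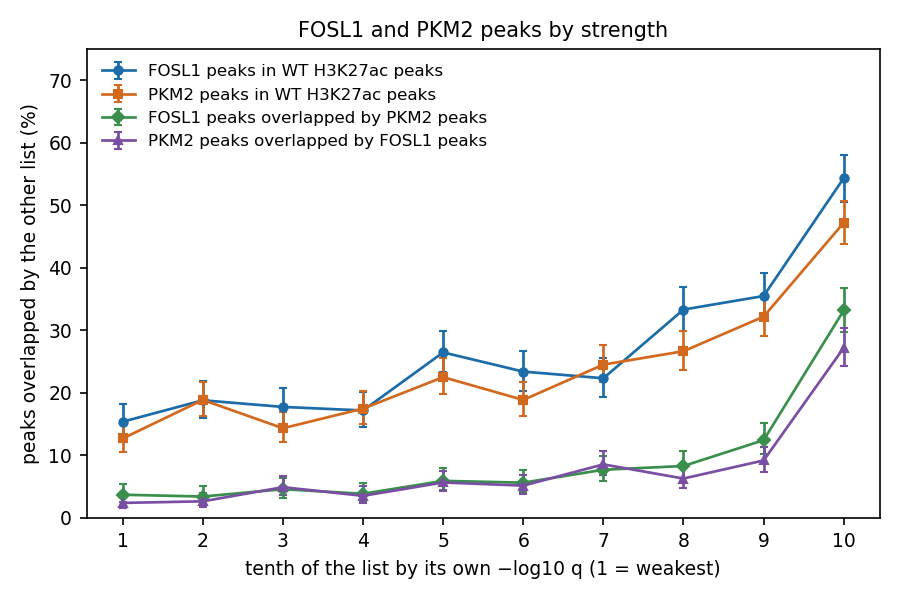
Percentage of FOSL1 and PKM2 peaks in each decile of a list (x axis, by the list's own −log10 q, 1 = weakest) overlapped by wild-type H3K27ac peaks or by each other (y axis), with 95% Wilson intervals as bars. Overlap between FOSL1 and PKM2 peaks reached 33.2% of FOSL1 peaks and 27.2% of PKM2 peaks in the strongest decile.

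Wild-type H3K27ac peaks that held a FOSL1 or PKM2 peak were found in K206R cells more often than the others. The share was 84.1% of 1788 peaks with FOSL1 and 59.1% of those without. It was 81.2% of 1873 peaks with PKM2 and 59.2% of those without, and 94.4% of 392 peaks with both (91.6 to 96.3). The 370 retained peaks with both are by definition the wild-type H3K27ac peaks called in all 4 libraries. Compared within deciles of H3K27ac score, the difference was 9.19 percentage points at FOSL1 peaks (7.68 to 10.7) and 9.20 points at PKM2 peaks (7.58 to 10.8). With the 392 peaks left out, a setting chosen after seeing the data, the differences were 9.08 and 9.12 points. Among H3K27ac peaks with a −log10 q of at least 10 in both lists, it was 0.415 points at FOSL1 peaks (-1.46 to 2.29) and 2.47 points at PKM2 peaks (0.921 to 4.02).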

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

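No paired analysis was possible because each group held 1 library. Of the 59 alternatives set for the main results before the data were examined, 26 left their result within its counting interval, or within 1.5 times a count, and 33 moved it. Of 51 set for single gene lists, 44 left the list in its place inside or outside the random range with no turn to the opposite sign. A median of 0 counted as no turn. Of the others, 6 changed the place or the sign, and 1 turned the sign of a list that had lain outside. Among the 6, the WNT list went from 48 to -20 bp with the same number of peaks, inside its range in both. Of the 16 chosen after seeing the data (peaks in all 4 libraries left out, H3K27ac peaks with both FOSL1 and PKM2 left out, q under 0.05, a promoter rule by coordinates and the thinning of K206R peaks), 7 moved their result. Most main results are shares or counts, which cannot change sign. The covered-length ratio stayed above 1 and the retention differences stayed positive in every alternative. The 3 alternatives of the AP-1 motif search were not run. Where nothing else is said, the cause was not tested. With a −log10 q of at least 10 in both lists, 93.9% of wild-type H3K27ac peaks were found in K206R and 40.5% of K206R peaks in wild type, the covered-length ratio was 2.41, and 156 genes had promoter H3K27ac in wild type alone, against 3002 in K206R alone. That cut was not adjusted for the difference in background level. Under that setting 58.8% of FOSL1 and 56.4% of PKM2 peaks lay in H3K27ac peaks, 86.3% of FOSL1 peaks overlapped PKM2 peaks, and retention differed by 2.47 points at PKM2 and 0.415 points at FOSL1 peaks. With the same number of peaks from each list, the shares were 55.6% for wild type in K206R, 55.2% for K206R in wild type, 11.3% for FOSL1 and 9.55% for PKM2 in H3K27ac. The covered-length ratio was then 1.14, and 0 of 17 gene lists lay outside their random range, against 2, the glycolysis and acyltransferase lists. The random ranges were not adjusted for the number of lists, so some can fall outside by chance. Within 2 kb, 2 lists lay outside, glycolysis and ribosomal proteins. At least 50% overlap gave 53.7%, 38.3%, 22% and 19.6% for the same shares and 6.60% for FOSL1 overlapped by PKM2, lower by construction, and 7.46 points for retention at FOSL1 peaks. Counting peaks within 1 kb gave 63.9%, 49.6%, 30.1%, 27% and 10.3%, higher by construction. Without standardisation, retention differed by 22 points at PKM2 and 25 points at FOSL1 peaks. Stitching within 5 kb gave 1062 K206R domains against 666 in wild type, turning the order of the genotypes (481 against 606), and 91.3% of wild-type domains overlapped. Keeping peaks near a TSS gave 786 K206R domains, and ranking by covered length gave 41.3% overlapped. In the 50 kb window 0 of 17 gene lists lay outside, and the median difference of acyltransferases and deacylases turned from -35 to 441 bp. Without peaks called in all 4 libraries, 22% of FOSL1 and 19.7% of PKM2 peaks lay in H3K27ac, and 3.72% of FOSL1 peaks overlapped PKM2, all lower by construction. With q under 0.05 in the binding list alone, 43.3% of FOSL1 and 36.9% of PKM2 peaks lay in H3K27ac, and 20.7% of FOSL1 peaks overlapped PKM2. With q under 0.05 in both lists, 13.3% of FOSL1 peaks overlapped PKM2. Thinning gave a covered-length ratio of 1.27, with the remaining peaks kept at their full length.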

Other observations

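The tests of depth and of regions called in every library were chosen after the results were seen, as was the comparison along chromosome 8. Beyond the sites described above, super-enhancer-like domains were assigned to several genes of the fixed lists in both genotypes. These were KLF4, ELF3, EHF and CLDN4 among colonic epithelial genes, MET and TGFBR2 among epithelial-mesenchymal transition genes, TEAD1, MYOF and GADD45A among YAP-TEAD targets, TCF7L2 among WNT genes, EPHA2 among vasculogenic mimicry genes, and DUSP5, EREG, ZFP36 and ZFP36L1 among immediate early genes. MBP and SYT1 of the neural and liver markers were in this group too. Domains assigned to PFKP and PKM of the glycolysis list, BNIP3L and DDIT4 of the hypoxia list, ANGPT2, IER2 and NEUROD1 were called super-enhancer-like in wild type and not in K206R, where fewer domains passed the cut, and these calls do not show a loss of signal. Those of PTPN14, WWTR1, RNF43, LAMA5 and PTK2 were called in K206R and not in wild type.

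Along chromosome 8, FOSL1 and PKM2 peaks with a −log10 q below 10 were denser beyond 50 Mb than in the first 40 Mb. The density was 4.32 against 1.93 peaks per Mb for FOSL1 (ratio 2.25, 1.76 to 2.87 by counting error) and 5.33 against 1.83 for PKM2 (ratio 2.92, 2.29 to 3.73). For wild-type H3K27ac the ratio was 1.67 (1.47 to 1.90) and for K206R H3K27ac 1.77 (1.57 to 1.99). No explanation for this was tested.

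The K206R list held more H3K27ac peaks than the wild-type list. A deeper K206R library as the whole cause is argued against by thinning, as far as the background level stands in for depth. At the wild-type background level and the same p threshold, K206R peaks still numbered 1.19 times the wild-type peaks (1.19 in the lowest and the highest of 20 thinnings, against a limit of 1.1). The background level also moves with the length to which fragments were extended, so a larger difference in depth stays open. Peaks were not called anew from thinned reads. For a difference between 2 single preparations, which stays open, K206R-only genes outnumbered wild-type-only genes in 81.3% of the gene lists with either, 13 of 16 (57.0 to 93.4), among them endothelial and blood cell markers. This count used the K206R peaks without thinning. Some genes, among them KDR and TIE1, are in more than 1 list, so the lists are not independent and the interval does not allow for that. Over all genes, 2833 were K206R-only and 1340 wild-type-only, so most lists would go this way whatever the cause. The count does not test whether the excess depended on function. Genotype and preparation cannot be told apart with 1 library each, and an effect of the K206R mutant remains an untested alternative.

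FOSL1 and PKM2 peaks coincided 31.9 times as often as random placements gave, and for the strongest peaks regions of high background in every library are a candidate explanation. Of the FOSL1 peaks with a −log10 q of at least 10, 74.5% were called in all 4 libraries (61.1 to 84.5) and 15.7% were promoters. For the weaker peaks, the odds ratio within deciles of H3K27ac score was 4.06 (3.55 to 4.64). This argues against active chromatin that draws both antibodies, as far as that score measures it, as the whole cause. The length of the H3K27ac peaks was not in the strata, and longer peaks have more room for both, so length stays open. Over all peaks, strong ones included, PKM2 peaks moved within 500 kb gave 4.10% of the observed overlap (at most 6.68%). This argues against regional peak density alone, with the peaks of each list placed independently. It cannot test copy number that raises calls of both antibodies at the same sites, which stays open. Joint presence of the proteins and local accessibility finer than the H3K27ac score also stay open, since no IgG library was analysed here.

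Most FOSL1 peaks, 73.5%, lay outside wild-type H3K27ac peaks. Chance calls at a loose threshold, if placed uniformly along the chromosomes, are argued against as the whole account of the weakest peaks. The weakest decile of FOSL1 peaks lay in H3K27ac peaks 11.3 times as often as random placements (9.43 to 13.4), or 15.4% against 1.36%. This excludes that the decile is made of uniformly placed calls alone and does not exclude that many of its peaks are. The placements cannot test background calls that favour open chromatin, and no IgG library was analysed here. No biological explanation was tested.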
